A study of Mus musculus with 4 samples.

How the data were processed

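Total RNA of lineage-negative, Kit-positive bone marrow cells from mice with JAK2V617F was depleted of ribosomal RNA and sequenced on the Illumina platform, per the labels' protocols. Reads were processed with STAR and Cuffdiff against mm10, per the submitters' processing notes; versions and gene annotation are not given in the sources used here. The authors deposited FPKM values, that is fragments per kilobase of transcript and 1000000 fragments, for 24340 genes in 4 libraries, named by gene symbol. Any scaling between libraries was Cuffdiff's and is not stated. A second deposited table holds the authors' comparisons of library pairs as log2 fold changes without a pseudocount. The authors' table also gives a test statistic, which is a score, with p-values and q-values per gene; the statistic and p-values were not used here. Its 2 columns of values per library were not used. Of the 6 comparisons in that table, 4 were used. Cuffdiff gave no estimate for 2 genes with too many fragments and 16 genes whose fit failed, per the file's status column.

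Each library was assigned to its group by the title given in the labels. With 1 library per group no spread within a group can be estimated, and no p-value was computed. An additive fit of genotype and drug, which would take their interaction as error, was not made. Ratios were taken on log2(FPKM + 1), which understates the change of low genes. Genes with a mean of at least 1 FPKM over the 4 libraries counted as measured, 10471 in all, and 10439 of them matched a name in the reference gene table, used for gene types and chromosomes. Genes at 2-fold or more were counted, and members of gene lists at 1.5-fold or more. The 39 gene lists for repair pathways, signalling, metabolism and blood cell types were fixed before the data were examined, as were the filter, the size rules and the rule for named genes. A list with at least 5 measured members was described by its median log2 ratio. Its place among the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression, is a description of these libraries. A list stood apart when its median fell in the outer 2.5% at either end. Of 33 lists tested in each comparison, 1.65 would stand apart by chance if list members were independent. Those that did so numbered 9 higher and 8 lower for the knockout without drug, 12 and 5 with drug, 6 and 7 for ruxolitinib in wild type, 2 and 5 in the knockout, and 5 and 8 for the difference. Mitochondrial transcripts were not analysed here, and replication-dependent histones had 3 measured genes and were not tested.

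The rule for named genes took, per comparison, the 6 highest and 6 lowest genes with at least 5 FPKM in a library, leaving out unnamed, small RNA and pseudogene symbols. It added up to 4 leading members of each list that stood apart, repair genes at 2-fold or more, and a fixed set around Tet2, Jak2, Brca1, Lig4, Parp1 and Dnmt3a, with Cish, Pim1, Socs2, Myc and Bcl2l1 for the drug. It gave 47 to 86 genes per comparison, of which the text describes a part. Dnmt3a lay between 9.31 and 10.4 FPKM in the 4 libraries. Sex-linked, mast cell and granule genes named for single libraries were chosen after their values were seen. Likeness of comparisons was described by Pearson and Spearman correlation across genes for pairs that share no library.

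Depth was estimated from genes with 1 annotated transcript longer than 1500 bases, after taking off 200 bases. Their lowest values fell near whole multiples of 0.0227, 0.0210, 0.0184 and 0.0191 FPKM for 1 kilobase in the wild-type control, wild-type ruxolitinib, knockout control and knockout ruxolitinib library. Of low values set aside for the check, between 79.0% and 85.1% lay within 0.15 of a whole multiple. This gives estimates of depth, with any scaling by Cuffdiff included, and not counts. At these depths 1 FPKM on a transcript of 1 kilobase is about 44.1 to 54.3 fragments. The steps were tested on simulated data for the knockout comparison without drug, with counting error only, over 10455 genes. There, 20.4% of genes changed 2-fold, 93.9% of genes changed 3-fold and 100% of genes changed 4-fold passed the 2-fold rule, and 0 of 10235 unchanged genes did. Every simulated transcript was taken as 1 kilobase long, so these rates do not apply to shorter transcripts such as small RNAs. A list shifted by a log2 ratio of 0.30 had a median of 0.25, and 4 of 100 unchanged lists stood apart.

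Alternatives planned before the data were examined were pseudocounts of 0.1 and 5, no filter on low values, a mean FPKM filter of 5, libraries centred on their median ratio, values summing to 1000000 per library (TPM), random lists not matched on expression, and a 3-fold rule. Counts over protein-coding genes, and over those off the X and Y chromosomes, were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Coordinates are those of the deposited table in mm10. Some genes are not reported here.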

Results

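The study asked how loss of Tet2, an enzyme that oxidises methylated cytosine, bears on DNA repair genes in myeloid cells driven by a mutant kinase. RNA was measured in mouse bone marrow cells that carried the activated kinase JAK2V617F and had been sorted as lineage-negative and Kit-positive, a gate that enriches for immature blood cells. The cells were Tet2 wild type or Tet2 knockout, and of each genotype 1 library came from control cells and 1 from cells given ruxolitinib, an inhibitor of the kinases JAK1 and JAK2. There were thus 4 libraries in 4 groups, and no difference given here has a replicate check. Between 10323 and 10375 genes reached 1 FPKM in each library. The steps between the lowest values pointed to 44100000 fragments in the wild-type control library and 47600000 in the wild-type ruxolitinib library. They pointed to 54300000 in the knockout control library and 52400000 in the knockout ruxolitinib library. These totals include any scaling by Cuffdiff, so they need not equal the fragments sequenced.

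Tet2 (chromosome 3, 133463677 to 133544390, mm10) was at 4.69 FPKM in the wild-type control, 5.05 in the wild-type ruxolitinib, 3.62 in the knockout control and 4.39 in the knockout ruxolitinib library. The knockout libraries were lower by a log2 ratio of -0.30 without drug and -0.17 with drug. A value for the whole gene does not see a deleted exon, so it neither checks nor contradicts the genotype labels. Sex-linked transcripts differed with genotype. Xist, the RNA that silences an X chromosome in females, was at 53.2 and 62.2 FPKM in the knockout control and ruxolitinib libraries and at 0.0241 and 0.0309 in the matching wild-type libraries. The Y-linked gene Ddx3y was at 21.3 and 18.7 FPKM in the wild-type libraries and at 0.0288 and 0.00886 in the knockout libraries. Genotype and sex of the animals were therefore not separated in these libraries.

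Transcripts of mast cell granules and of the IgE receptor were among the most abundant in all 4 libraries. The chymase Cma1 (chromosome 14, 55941451 to 55944661) was at 13677 FPKM in the wild-type control, 15834 in the wild-type ruxolitinib, 8289 in the knockout control and 10118 in the knockout ruxolitinib library. The IgE receptor chain Fcer1a (chromosome 1, 173221271 to 173227229) lay between 3451 and 6008 FPKM, the tryptase Tpsb2 between 3026 and 3692 and the stem cell factor receptor Kit between 421 and 647. Mpo, the peroxidase of granulocyte progenitors, did not exceed 1.31 FPKM, and the elastase Elane did not exceed 0.0256. The carboxypeptidase Cpa3 was listed at 0 in all 4 libraries, where the authors' deposited table gives no usable estimate. The lists for mature neutrophils, B cells, T and NK cells and stroma had fewer than 5 measured genes and were not tested.

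Without drug, the knockout library had higher levels of genes for DNA replication, mitosis, homologous recombination and ribosome biogenesis than the wild-type library, and lower levels of cytokine-signalling and immediate early genes. Of 28 DNA replication genes, 25 were at least 1.5-fold higher and 0 were as far lower, with a median log2 ratio of 0.75. They included the replication licensing factors Cdt1, at 16.3 FPKM in wild type and 31.3 in knockout, and Cdc6, at 4.62 and 9.46. All 23 mitosis genes had positive ratios, with a median of 0.44, among them the topoisomerase Top2a at 74.1 and 115.8 FPKM. The medians of both lists lay above all 10000 matched random lists.

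Homologous recombination, which repairs double-strand breaks from a sister chromatid, was the repair pathway with the highest median, at 0.43. Of its 26 measured genes, 6 were at least 1.5-fold higher and 0 were as far lower. Brca1 (chromosome 11, 101488764 to 101551955) was at 6.80 FPKM in wild type and 11.1 in knockout, a log2 ratio of 0.64. The nuclease Dna2 was at 5.55 and 10.96 FPKM and the translocase Rad54l at 11.5 and 20.05. The Fanconi anaemia pathway, which handles DNA crosslinks, had a median of 0.35 over 14 genes, with Fanca at 4.15 and 8.30 FPKM. Mismatch repair had a median of 0.37 over 7 genes and the DNA damage checkpoint 0.31 over 16 genes, with Msh6 at 12.6 and 21.1 FPKM and the checkpoint kinase Chek1 at 4.79 and 8.34. These 4 repair and checkpoint lists lay above the range of random lists.

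Classical non-homologous end joining, which rejoins broken ends directly, had a median log2 ratio of -0.02 over 12 genes, or 0.12 with values rescaled to TPM, and lay within that range in both cases. Its ligase Lig4 (chromosome 8, 9970020 to 9976323) was at 2.18 FPKM in wild type and 2.35 in knockout. Alternative end joining and single-strand break repair had a median of 0.11, base excision repair 0.16 and nucleotide excision repair 0.03, all within the range of random lists. Parp1 (chromosome 1, 180568975 to 180601254), the polymerase that marks strand breaks and is the target of PARP inhibitors, was at 37.7 and 49.6 FPKM, a log2 ratio of 0.39. The authors' deposited table gave q-values of 0.000746 for Brca1, 0.0255 for Parp1 and 0.802 for Lig4 in this comparison. Those values compare the libraries and not the genotypes.

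Ribosome biogenesis genes linked to Myc were all higher in the knockout library, with 24 of 24 positive ratios and a median of 0.44, though none reached 1.5-fold. The list of cytosolic ribosomal proteins had a median of -0.05 over 31 genes, within the random range. The nucleolar proteins Nop58 and Nop56 were at 78.3 and 38.7 FPKM in wild type and 116.1 and 56.9 in knockout. Cholesterol synthesis genes had a median of 0.17 and nuclear-encoded respiratory chain genes a median of 0.15, both above the random range. The list of STAT5 and cytokine feedback targets, called STAT5 targets here, had a median of -0.41. STAT5 is a transcription factor downstream of JAK2, and not every listed gene is specific to it. Of the 17 genes, 7 were at least 1.5-fold lower and 1 as far higher. The phosphatase Dusp5 was at 9.86 and 4.23 FPKM, the feedback inhibitor Socs3 at 19.0 and 9.77 and cyclin Ccnd2 at 247 and 145. Jak2 itself (chromosome 19, 29251803 to 29313080) was at 36.8 and 24.5 FPKM, a log2 ratio of -0.57. Immediate early genes had a median of -0.48, with 8 of 20 at least 1.5-fold lower, among them Fosb at 21.3 and 4.18 FPKM and Egr2 at 21.8 and 4.32. The wild-type control library held the highest value of the 4 libraries for 15 of these 20 genes.

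Further lists that stood apart on the lower side were the NF-kB genes at -0.34, interferon-stimulated genes at -0.27, MHC class II genes at -0.34, megakaryocyte and platelet genes at -0.29, stem cell genes at -0.23 and the BCL2 family at -0.19. The mast cell list had a median of -0.22, with 14 of 18 genes negative, within the random range. The granulocyte-monocyte list had a median of -0.22 over the 8 of 17 genes that passed the filter, also within that range. Over all 17 genes its median FPKM was higher in the knockout, at 0.111 in the wild-type control and 1.62 in the knockout control library. The filtered median therefore does not describe its low members. The interferon, MHC class II, stem cell, BCL2 and cholesterol calls were lost under at least 1 alternative setting. Among single genes, the chemokine Ccl6 was at 0.654 FPKM in wild type and 17.1 in knockout, the basophil and mast cell protease Prss34 at 0.266 and 11.3, and the mast cell receptor Mrgprb2 at 0.77 and 10.01. The decoy receptor Il1r2 was at 38.5 and 3.48 FPKM and the adaptor Fblim1 at 17.3 and 0.742. At 2-fold or more, 125 of 10471 measured genes were higher and 178 lower; rescaled to TPM, the larger share was higher, 193 against 165. Of the 9927 protein-coding genes, 9613 of which lay off the sex chromosomes, 58 were higher and 112 lower. Of these 170, 162 lay off the sex chromosomes. Of 234 small RNA genes, whose short transcripts make FPKM unstable, 114 passed the same rule.

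**Figure D1:**
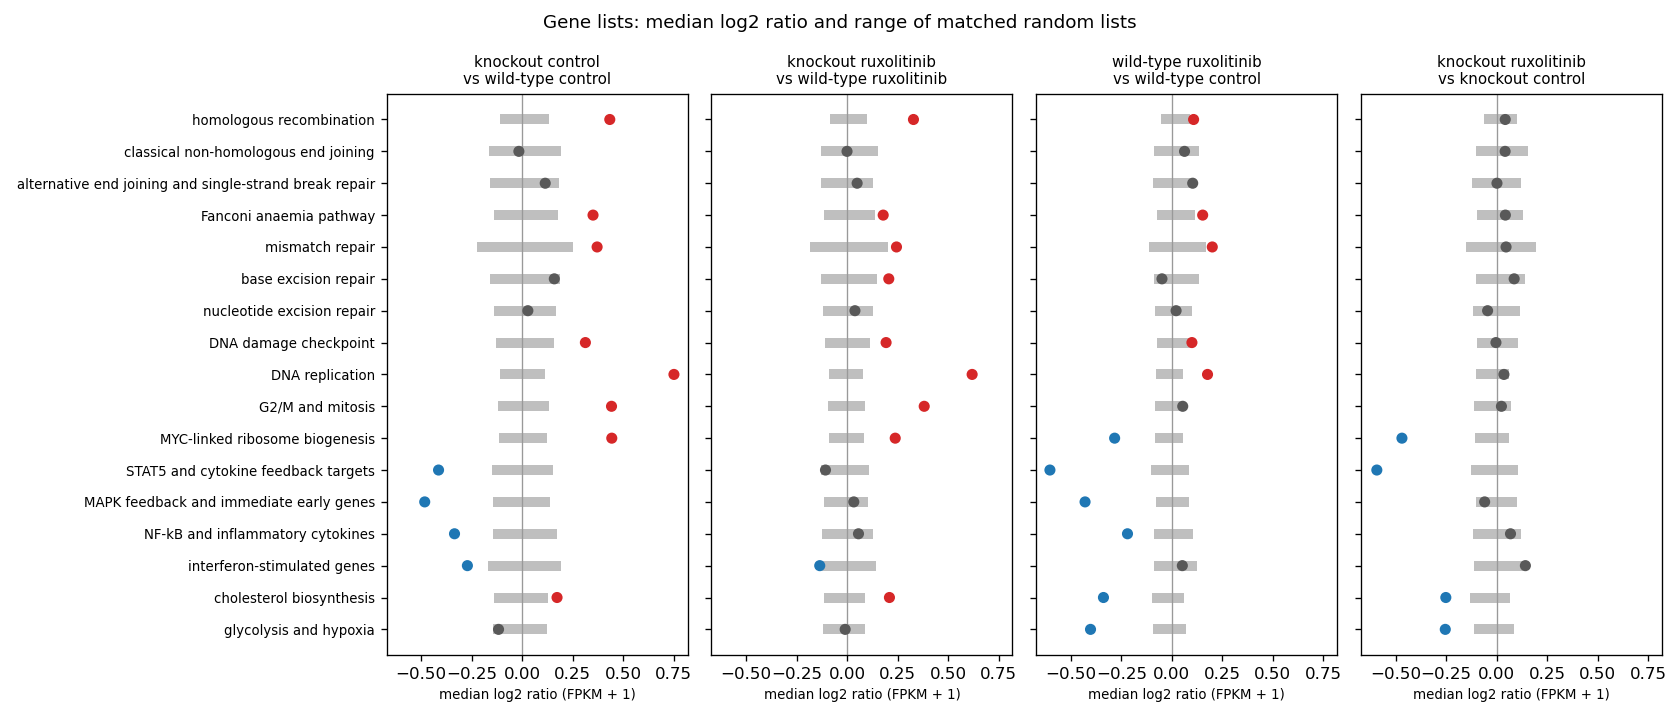
Median log2 ratio of FPKM + 1 (x axis) of 17 gene lists (y axis) in 4 comparisons of 1 library each, with grey bars for the central 95% of 10000 random lists matched on mean expression. Red points lie above and blue points below that range, with homologous recombination at 0.43 and 0.33 in the knockout comparisons and STAT5 targets at -0.60 and -0.59 in the ruxolitinib comparisons.

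With ruxolitinib, the knockout library again had higher levels of DNA replication, mitosis and homologous recombination genes than the wild-type library, while the STAT5 and immediate early lists no longer stood apart. DNA replication had a median log2 ratio of 0.62, with 18 of 28 genes at least 1.5-fold higher, and mitosis a median of 0.38. The homologous recombination median was 0.33, with 1 of 26 genes at least 1.5-fold higher. Brca1 was at 8.11 FPKM in wild type and 12.2 in knockout, Rad54l at 13.05 and 20.7, and Bard1, the partner of Brca1, at 3.15 and 5.07. The Fanconi pathway had a median of 0.18, mismatch repair 0.24, base excision repair 0.21 and the checkpoint list 0.19, all above the random range. The uracil glycosylase Ung was at 9.17 and 14.3 FPKM. Classical end joining was within the range, with a median of -0.00, or 0.13 rescaled to TPM, and Lig4 at 2.33 and 2.43 FPKM.

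The STAT5 targets had a median of -0.11 and immediate early genes 0.03 in this comparison, both within the range of random lists. Ribosome biogenesis genes had a median of 0.24, again with 24 of 24 positive, and cholesterol synthesis genes 0.21. The list of Hox and leukaemia-linked transcription factors had a median of -0.17, with the haematopoietic factors Lyl1 at 120.6 and 72.5 FPKM and Lmo2 at 36.8 and 22.2; of its 17 genes, 2 were at least 1.5-fold higher and 2 as far lower. Megakaryocyte genes had a median of -0.19, with the tetraspanin Cd9 at 227.1 and 112.0 FPKM, and stem cell genes a median of -0.18, with Txnip at 269.8 and 160.3. Interferon-stimulated genes at -0.14 and MHC class II genes at -0.31 also stood apart, as did ATF4 genes at 0.09, respiratory chain genes at 0.08 and the monocyte list at 0.44, where 4 of 7 measured genes were positive and 3 were at least 1.5-fold lower. Each of these 5 calls, and those of the Fanconi, base excision, megakaryocyte and transcription factor lists, was lost under at least 1 alternative setting. Jak2 was at 35.1 and 24.9 FPKM and Parp1 at 39.4 and 48.5. At 2-fold or more, 124 genes were higher and 141 lower, of which 66 and 74 were protein-coding; rescaled to TPM, 179 were higher and 131 lower. Xist and the Y-linked genes again split with genotype.

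The knockout differences without and with drug come from separate pairs of libraries, although the labels do not say whether the libraries of a genotype came from the same animals. Across 9927 protein-coding genes, a subset chosen after seeing the data, the log2 ratios had a Pearson r of 0.87 and a Spearman rho of 0.84. Genes are not independent replicates, so these values describe the libraries only. At 2-fold or more, 44 genes were higher in both pairs, against 0.386 for independent lists of those sizes, and 65 were lower in both, against 0.835. Over all measured genes r was 0.34, and 26 genes were at 2-fold or more in opposite directions.

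**Figure D2:**
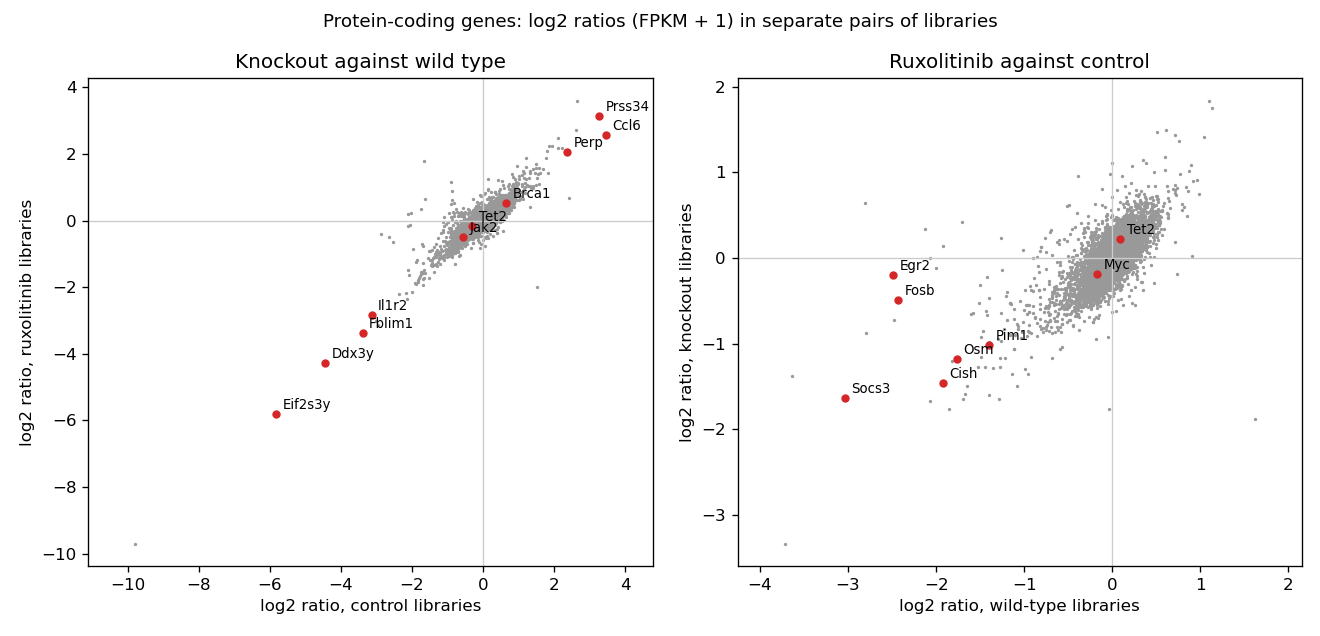
Log2 ratios of FPKM + 1 of 9927 protein-coding genes, each grey point 1 gene, with named genes in red. Left, knockout against wild type in control (x axis) and ruxolitinib libraries (y axis), r = 0.87. Right, ruxolitinib against control in wild-type (x axis) and knockout libraries (y axis), r = 0.71. In the right panel, Egr2 and Fosb lie low on the x axis only. The lowest point on the left, at -9.78 on the x axis, is Rpl34-ps1, listed at 0 in both knockout libraries. Its symbol is that of a pseudogene, but it counted as protein-coding by the reference genes used.

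In wild-type cells, the ruxolitinib library had lower levels of STAT5 targets, immediate early genes, inflammatory cytokines and genes of glycolysis, cholesterol synthesis and ribosome biogenesis than the control library. The STAT5 list had a median log2 ratio of -0.60, with 9 of 17 genes at least 1.5-fold lower and 1 as far higher. Cish (chromosome 9, 107296689 to 107301961), a feedback inhibitor of cytokine receptors, was at 174.1 FPKM in control and 45.1 with drug. The kinase Pim1 was at 148.4 and 55.5 FPKM, Socs1 at 111.4 and 30.0, Socs3 at 19.0 and 1.43 and the cytokine Osm at 97.2 and 27.8. Socs2 was at 29.4 and 19.0 FPKM and the survival gene Bcl2l1 at 41.6 and 31.1. Myc was at 64.2 and 57.0 FPKM, a log2 ratio of -0.17.

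Immediate early genes had a median of -0.43, with 9 of 20 at least 1.5-fold lower, including Fosb at 21.3 and 3.13 FPKM and Nr4a1 at 37.8 and 6.73. This change and that of the knockout without drug share the wild-type control library, which was at least 1.5-fold above each other library for 8 of these genes, a number that was 0 for each other library. The NF-kB list had a median of -0.22, with 2 of 14 genes at least 1.5-fold lower and 1 as far higher. The chemokine Ccl4 was at 6.39 and 0.951 FPKM, and Tnfaip2 at 17.1 and 28.7. The wild-type control library held the highest value of the 4 libraries for 11 of these 14 genes. Glycolysis and hypoxia genes had a median of -0.40, with the mitophagy receptor Bnip3 at 18.0 and 6.20 FPKM and Vegfa at 14.4 and 6.76. Cholesterol synthesis genes were lower in 21 of 21 cases, with a median of -0.34. Ribosome biogenesis genes were lower in 24 of 24 cases, with a median of -0.28. ATF4 and unfolded protein response genes were lower in 22 of 22, with a median of -0.26. These shifts were small: at 1.5-fold or more, 1 cholesterol synthesis gene, 0 ribosome biogenesis genes and 1 ATF4 gene were lower. The serpin Serpina3g was at 92.4 and 6.09 FPKM and the cytokine Il13 at 17.7 and 0.50.

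Some lists had small positive medians with drug, namely DNA replication at 0.18, mismatch repair at 0.20, the Fanconi pathway at 0.15, homologous recombination at 0.11, the checkpoint list at 0.10 and mast cell genes at 0.10. None of the genes in the first 5 of these lists reached 1.5-fold, and the mismatch repair, homologous recombination, checkpoint and mast cell calls were lost under at least 1 alternative setting. Brca1 was at 6.80 and 8.11 FPKM. The surface protein Cd52 was at 42.3 and 94.1 FPKM. Of protein-coding genes, 4 were at least 2-fold higher and 71 lower, and over all measured genes 54 were higher and 135 lower.

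In knockout cells, the ruxolitinib library had lower STAT5 targets, ribosome biogenesis, cholesterol, glycolysis and ATF4 genes than its control, while immediate early genes did not stand apart. The STAT5 median was -0.59, with 9 of 17 genes at least 1.5-fold lower and 1 as far higher. Cish was at 113.8 FPKM in control and 40.7 with drug, Pim1 at 98.6 and 48.3, Socs1 at 115.8 and 33.5 and the kinase Pim2 at 12.97 and 3.64. Ribosome biogenesis genes had a median of -0.47, all 24 with negative ratios. This list also holds the polyamine enzymes Srm and Odc1, at 165.5 and 25.6 FPKM in control and 100.2 and 15.6 with drug. Cholesterol synthesis had a median of -0.25, glycolysis and hypoxia -0.25 and ATF4 genes -0.28. Immediate early genes had a median of -0.06, with Fosb at 4.18 and 2.70 FPKM and Nr4a1 at 8.46 and 7.99.

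The homologous recombination list had a median of 0.04 and DNA replication 0.04, both within the random range, and Brca1 was at 11.1 and 12.2 FPKM. Mast cell genes had a median of 0.15, with the protease Mcpt2 at 794 and 2043 FPKM. The monocyte list had a median of 0.56 over 7 measured genes, with lysozyme Lyz2 at 2.36 and 6.61 FPKM, a call lost without the filter on low values. Of protein-coding genes, 16 were at least 2-fold higher and 33 lower, and over all measured genes 66 were higher and 96 lower. Across protein-coding genes, the ruxolitinib ratios of the wild-type and knockout pairs had a Pearson r of 0.71 and a Spearman rho of 0.72. At 2-fold or more, 25 genes were lower in both, against 0.236 for independent lists, and 3 were higher in both, against 0.00645. Over all measured genes r was 0.16, and 24 genes were at 2-fold or more in opposite directions.

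**Figure D3:**
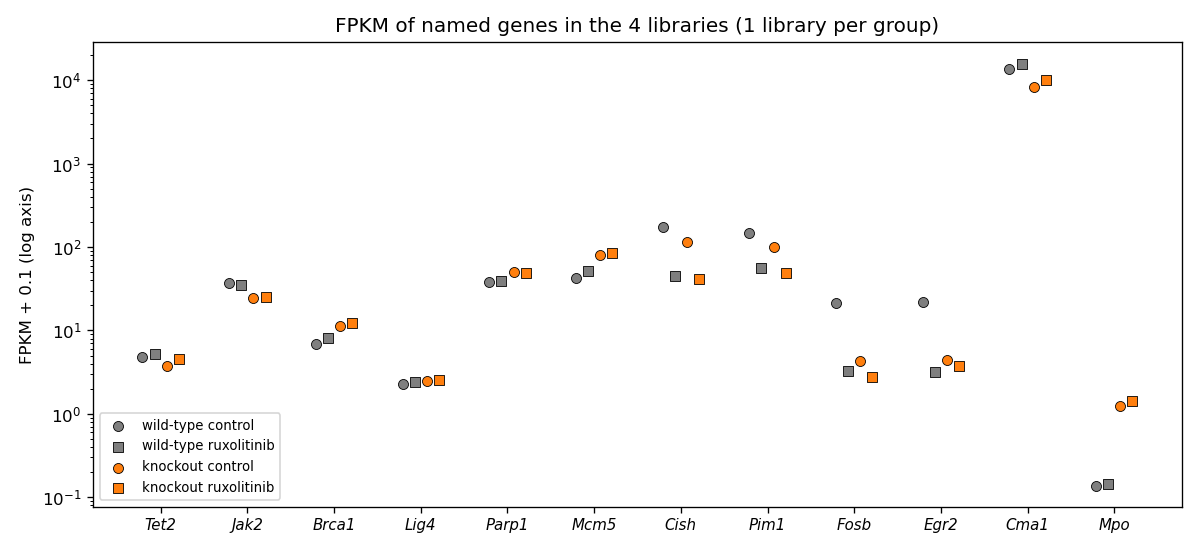
FPKM + 0.1 on a log axis (y axis) of 12 named genes (x axis) in the 4 libraries, each symbol 1 library, circles for control, squares for ruxolitinib, grey for wild type and orange for knockout. Cish and Pim1 are lower in both ruxolitinib libraries, Brca1 is higher in both knockout libraries, and Fosb at 21.3 FPKM is highest in the wild-type control library.

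The difference between the knockout and wild-type responses was greatest, by list median, for immediate early genes. Their median difference in log2 ratio was 0.52, with 19 of 20 genes above 0, and Egr2 at 2.29, Nr4a1 at 2.25 and Fosb at 1.94. The monocyte list followed at 0.36 over 7 genes, NF-kB genes at 0.34 with 14 of 14 above 0 and the highest value in the wild-type control library for 11, glycolysis and hypoxia at 0.21 and STAT5 targets at 0.10. The wild-type control library was at least 2-fold above each other library at 23 protein-coding genes. The matching numbers were 0 for the wild-type ruxolitinib, 6 for the knockout control and 2 for the knockout ruxolitinib library. Ribosome biogenesis genes differed by -0.19, with 0 of 24 above 0, DNA replication by -0.15 and homologous recombination by -0.08. Mismatch repair differed by -0.16, the checkpoint and alternative end joining lists by -0.10 each, the Fanconi pathway by -0.09 and respiratory chain genes by -0.07. The homologous recombination and Fanconi calls were lost with a mean FPKM filter of 5. Socs2 differed by 0.01, Bcl2l1 by -0.04 and Myc by -0.02. Over all measured genes, the difference was at least 2-fold and positive, that is a higher ratio in the knockout, for 105 and negative for 88. Among protein-coding genes, a subset chosen after seeing the data, these counts were 25 and 2. The difference rests on 4 single libraries and was not tested.

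By the authors' deposited table, 2167 genes differed between the control libraries of the genotypes, 1066 higher and 1101 lower in the knockout, and 1548 between the ruxolitinib libraries. The same table called 735 genes for ruxolitinib in wild type, 269 higher and 466 lower, and 1085 in the knockout, 549 higher and 536 lower. The highest q-value it called was 0.0499. With 1 library per group these calls compare libraries, not conditions.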

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

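All tests in this part were chosen after the values were seen. Among 205 named protein-coding genes and 33 lists, genes were sought whose ratio was at least 1.5-fold in opposite directions under the same contrast; the differences were not tested. The knockout ratio was -0.90 without drug and 1.16 with drug for Ccl4. For Egr1, an immediate early transcription factor, it was -0.87 and 0.63. For Il13 it was -1.62 and 0.64, and the FPKM in the wild-type control, wild-type ruxolitinib, knockout control and knockout ruxolitinib libraries were 17.7, 0.50, 5.05 and 1.34. Rnaset2a had a knockout ratio of -1.67 without drug and 1.78 with drug, and a ruxolitinib ratio of -2.81 in wild type and 0.64 in the knockout; it has a near-identical neighbour, Rnaset2b, so its reads are uncertain. With a knockout ratio below 0 without drug and above 0 with drug, only the wild-type control or knockout ruxolitinib library can hold the highest value. In these 4 genes it was the wild-type control library, which is therefore partly set by how they were picked.

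Mast cell transcripts were among the most abundant in all 4 libraries, where between 9 and 11 of the 25 genes of the mast cell list were among the 100 most abundant genes. Granulocyte-monocyte progenitors holding a minority of mast cells would bring their own abundant transcripts, yet the median of the granulocyte-monocyte list did not exceed 1.62 FPKM; an earlier form of this test, on the highest of 4 granule genes, gave 108 FPKM for Ctsg, which mast cells also make. A minority among stem or megakaryocyte progenitors was not tested and stays open: their lists had medians of at most 3.31 and 8.19 FPKM, yet the stem cell marker Ly6a reached 1033 and the megakaryocyte integrin Itga2b 743 FPKM. The median of the mast cell list was at least 11.5 times that of any other lineage list in each library. Mostly mast cell-like cells would give this, but it draws on the same abundant genes and adds no separate support. Outgrowth in culture after the sort cannot be told apart from cells present in the marrow, since the labels give no culture time, and the sort on Kit would not remove mast cells, with Kit at 421 FPKM or more. In the mast cell list 3 of 25 genes also belong to another list.

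Sex-linked transcripts split with genotype. Of the protein-coding genes at 2-fold or more, 95.3% lay off X and Y, so genes on X and Y were few among them. Since 9613 of all 9927 measured protein-coding genes lay off X and Y, nearly any set of genes would show such a share. It does not bear on whether sex shaped the rest. A mixture of male and female cells is argued against by values of at most 0.0360 FPKM for Y-linked genes in the knockout and for Xist in the wild-type libraries. Sex differences of the 162 genes on other chromosomes cannot be told apart from loss of Tet2, since no genotype has libraries of both sexes.

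Homologous recombination genes were higher in the knockout without drug, with a median log2 ratio of 0.43. A rise of every repair pathway alike is argued against by the end joining median of -0.0168, whose members had an SD of 0.23. A higher share of cycling cells may be a source of the difference, since 26 random genes of replication and mitosis had a central median of 0.61 and the repair list lay at percentile 0 of such sets, that is no higher than the cycle genes. An effect of Tet2 loss on repair genes beyond the cell cycle stays open, as do sex and differences between single animals, and no technical cause in 1 library could be checked by a replicate.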

How the results depend on the processing

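No paired analysis was made, since each comparison has 1 library per group. The additive fit of genotype and drug, which would take their interaction as error, was not made either. The counts over protein-coding genes were chosen after seeing the data. For the knockout without drug, the count of genes at 2-fold or more was 303, and it was 186 with a pseudocount of 5, 198 with a mean FPKM filter of 5, 160 at 3-fold, 170 for protein-coding genes and 162 for those off X and Y. With drug it was 265, against 148, 174, 143, 140 and 130 in the same order. For ruxolitinib in wild type it was 189, against 122 at 3-fold, 75 for protein-coding genes and 73 off X and Y. In the knockout it was 162, against 100, 49 and 48. For the difference of the responses it was 193, against 27 for protein-coding genes and 27 off X and Y. The filter and the gene classes leave fewer genes to count, 3-fold is a stricter rule, and a pseudocount of 5 shrinks the ratios. The Pearson r moved from 0.34 to 0.87 for the knockout ratios and from 0.16 to 0.71 for the ruxolitinib ratios with protein-coding genes, where small RNA genes were left out.

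Rescaling to TPM moved the median of all genes to 0.15 for the knockout without drug, from 0.00, and to 0.13 with drug, from 0.00. The split of higher against lower genes became 193 to 165, from 125 to 178, and 179 to 131, from 124 to 141. The end joining median in the knockout comparisons changed sign under it, to 0.12 and 0.13, and stayed within the range of random lists. Homologous recombination in both knockout comparisons and STAT5 targets in both ruxolitinib comparisons stood apart in the same direction under every setting run. Over the end joining list, the lists that stood apart and all settings, 584 results kept their side of the range and 32 lost it, 10 of these with no filter on low values and 6 with the filter of 5. In 0 cases did a list that stood apart change direction. Of the leading and fixed named genes, 332 ratios moved by less than 1.5-fold and 88 by more, with no change of direction for a gene past 1.5-fold. Depth limits the low genes, since 1 fragment of a 1 kilobase transcript is worth about 0.0184 to 0.0227 FPKM.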

Other observations

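The mast cell and basophil proteases did not differ with genotype as a block. In the knockout control library Mcpt8, a basophil protease, was at 276.6 FPKM against 94.4 in the wild-type control, whereas Mcpt1 was at 165.5 against 531.2 and Cma1 at 8289 against 13677. Tpsb2 was at 3026 and 3063 FPKM in these libraries. Mrgprb2, a receptor through which mast cells sense peptides and drugs, was at 10.01 FPKM in the knockout control and 0.77 in the wild-type control. The related receptor Mrgprb1 was at 6.48 and 0.225 FPKM in the same order. Mcpt8 and Tpsb2 were chosen after their values were seen. With ruxolitinib Mcpt2 was higher in both genotypes, by a log2 ratio of 0.75 in wild type and 1.36 in the knockout.

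The ribosomal RNA precursor Rn45s was at 476 FPKM in the wild-type control, 444 in the wild-type ruxolitinib, 132 in the knockout control and 310 in the knockout ruxolitinib library. The most abundant entry, Mir6236, took between 4.51% and 7.56% of the summed FPKM.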
